A study of Rattus norvegicus with 6 samples.

How the data were processed

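Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats, 3 given corn oil and 3 given anthraquinone at 1000 mg/kg/day for 4 weeks. The animals were 5 weeks old at purchase, per the labels' protocols. Each animal was hybridised to its own 1-colour (Cy3) Agilent array. Groups and replicate numbers were taken from the sample titles. The series' design text states that each group holds 3 biological replicates. P-values for single genes therefore measure the spread between these animals, and the number of arrays limits the precision. The list tests at a preset correlation between genes, described below, depend also on the number of genes in a list. Genes are not independent replicates, so p-values of those tests do not measure that spread alone.

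The deposited scanner files hold the intensity of each spot on a linear scale, written by Agilent Feature Extraction 10.7.1.1 per the file headers (version 10.7 per the submitters' processing notes). The processed intensity used here was corrected for background and spatial trend by that software before deposit, per the file headers, and was not scaled between arrays. Each array held 62976 spots, of which 61657 were non-control probes. The authors also deposited a value table of intensity per probe. Set against the scanner values, each of its columns was the processed intensity divided by that array's 75th percentile. Between 90.7 and 97.0% of probes lay within 0.01 log2 of 1 constant per array, and the values are linear and not centred by gene. The column medians were 0.109, 0.113 and 0.114 for corn oil replicates 1, 2 and 3 and 0.109, 0.111 and 0.110 for anthraquinone replicates 1, 2 and 3. No header states the scale of that table.

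The log2 processed intensity minus each array's 75th percentile over non-control probes was used. Between 2 and 13 spots per array carried the scanner software's non-uniformity or population outlier flags and were left out. A probe was tested if the software called it well above background on all arrays of at least 1 group, which 41310 probes met. Probes were named by matching their accession, without version, to the RefSeq table of rat assembly GRCr8. That table gave a symbol to 27460 of the 61657 probes (15284 symbols) and to 27348 of the 29123 probes with a curated messenger RNA accession. It was used for names only, since the arrays were designed on another assembly per the file headers. Each gene was represented by its brightest probe, and the 20832 unnamed probes that passed stood for themselves. This gave 32663 gene entries, 11831 of them with a symbol.

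Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment over all entries at 0.05. The 28 gene lists and 22 cell type marker lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the 50 lists. Camera with an estimated correlation and fry were run beside it. Of 1209 symbols written in the lists, 1207 were found in the table. Members are counted both over all genes tested and adjusted over the list alone. For each list, 10000 random lists matched on mean signal in 50 bins were drawn.

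The genes named were fixed by rule before the data were examined. The rule takes up to 12 increases and 12 decreases past the threshold that were above background in both groups without overlap. It adds up to 6 per direction that were above background in 1 group only. From each list it takes up to 3 members per direction past the threshold, or otherwise the member with the largest change. A fixed set of toxicity and kidney genes was added whatever its result. Members past the test adjusted over the list alone are named as well and were chosen after their values were seen. Some members that met these rules are not reported here. For a probe below background in a whole group, the fold is a lower bound, with each dim array set to the higher of its own value and the lowest signal among probes well above background. Of the fixed set, Mki67, Top2a and Slc12a1 had no probe matched to their symbol and were not analysed here.

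The alternatives were other scalings, no filter or a stricter filter on dim probes, other ways to combine probes, the deposited value table, other variance models, array weights, blocks for slide, row on the slide and replicate number, other thresholds, and each array left out. Cyclic loess was added after seeing the data. The planned normexp correction (offset 50) was run on median spot signals, because the planned form needs mean spot signals and the scanner columns read here hold medians. This was also decided after seeing the data. The procedure was tested on simulated data with the means and spread of the 32649 complete entries. It recovered 10% of 50 genes changed by 0.5 on the log2 scale, 74% of 50 changed by 1, 98% of 50 changed by 2 and 100% of 50 changed by 3. Of 151 simulated calls 8 were false. The simulated values were independent and normal with each entry's moderated variance, so outlying animals and correlation between genes were not simulated. These shares may therefore overstate recovery in the real data.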

Results

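The arrays compared the renal cortex of rats dosed with anthraquinone, a tricyclic quinone, with that of rats given the corn oil vehicle, with 3 animals in each group. The question given by the series is which genes change their expression in this tissue. The 75th percentile of the processed intensity was 1190, 903 and 956 in corn oil replicates 1, 2 and 3 and 880, 866 and 844 in anthraquinone replicates 1, 2 and 3. The share of probes well above background was 68.7, 70.5 and 70.7% in corn oil and 65.0, 64.2 and 66.1% in anthraquinone. Arrays of the same group correlated at 0.993 to 0.994 (corn oil) and 0.991 to 0.993 (anthraquinone), and arrays of different groups at 0.988 to 0.993, across genes, which are not independent replicates. The first principal component held 38.9% of the variance and placed the corn oil arrays at -33.91, -28.14 and -23.97 and the anthraquinone arrays at 8.07, 33.68 and 44.27. The second component held 18.1% and placed anthraquinone replicates 1, 2 and 3 at -12.66, -30.37 and 34.17. Corn oil replicate 1 lay alone on its slide and scan day, and the other 5 arrays shared a slide. Corn oil replicates 2 and 3 lay in row 1 and the remaining arrays in row 2.

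Anthraquinone raised Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, and Nqo1, which encodes a quinone reductase, and lowered Glyatl1, which encodes a glycine N-acyltransferase-like enzyme. Hmox1 was 4.39-fold higher, moving from -1.49 ± 0.25 to 0.64 ± 0.15 on the normalized log2 scale (SD, n = 3 per group, limma adjusted p = 0.0308). Nqo1 was 3.53-fold higher, from -2.47 ± 0.16 to -0.65 ± 0.17 (SD, n = 3 per group, limma adjusted p = 0.0308). Glyatl1 was 2.72-fold lower, from -2.02 ± 0.04 to -3.46 ± 0.13 (SD, n = 3 per group, limma adjusted p = 0.0308). The values of the groups did not overlap for any of these genes. In all, 9 of 32663 gene entries passed, 5 higher and 4 lower, and 3 of the 9 had a symbol. Among those without one, probe A_44_P802347 was not well above background on any corn oil array and was at least 6.51-fold higher with anthraquinone (limma adjusted p = 8.4e-05), and probe A_64_P150466 was 4.55-fold higher. Probe A_44_P714639 was 6.66-fold lower, with 2 of the 3 anthraquinone arrays well above background, and probe A_44_P513075 was 2.49-fold lower. With the normexp correction the log2 values of A_44_P802347 and A_44_P714639 were 1.45 and -1.39, and those of A_64_P150466 and A_44_P513075 were 0.78 and -0.65 and no longer passed (limma adjusted p = 0.0754 and 0.0650). At an unadjusted p under 0.05, 5593 entries differed, 3081 higher and 2512 lower, where chance alone gives 1633.

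The count moved with every array left out. It was 2 without corn oil replicate 1, 1 without corn oil replicate 2, 25 without corn oil replicate 3, 1 without anthraquinone replicate 1, 1 without anthraquinone replicate 2 and 4 without anthraquinone replicate 3. With the slide as a block, which is the same test as leaving out corn oil replicate 1, so that the slide and the loss of 1 array are not told apart, Hmox1 differed by 1.99 ± 0.11 (SE, limma adjusted p = 0.0928), Nqo1 by 1.79 ± 0.15 (limma adjusted p = 0.175) and Glyatl1 by -1.44 ± 0.11 (limma adjusted p = 0.167), and 2 entries passed. Row 1 holds corn oil arrays only, so a comparison within rows leaves corn oil replicate 1 as the only control and tests nothing about the row. Median scaling gave 5 higher and 1 lower, and the normexp correction, in a form chosen after seeing the data, gave 7 higher and 9 lower.

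**Figure D1:**
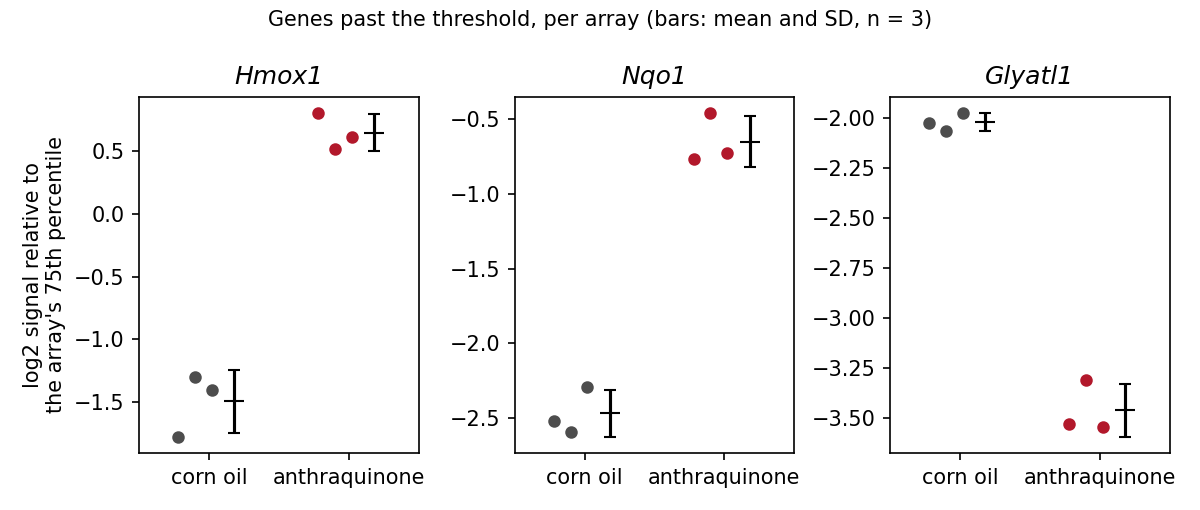
Normalized log2 signal (vertical axis, relative to each array's 75th percentile) of Hmox1, Nqo1 and Glyatl1 on each corn oil array (grey points) and anthraquinone array (red points), with the mean and SD of 3 arrays as black bars. Hmox1 was 4.39-fold and Nqo1 3.53-fold higher with anthraquinone, Glyatl1 was 2.72-fold lower, and the groups do not overlap.

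Targets of Nrf2, the transcription factor that induces antioxidant and detoxifying enzymes, rose as a list, with a median log2 change of 0.42 over 33 measured members (camera adjusted p = 1.4e-05, and adjusted p = 0.579 with an estimated correlation). The median was 0.26 without anthraquinone replicate 3 and 0.22 after quantile normalization (adjusted p = 6.8e-04). Over all genes tested 2 members rose, Hmox1 and Nqo1. When adjusted over the list alone, 9 rose and 0 fell. The others, chosen like all such members below after their values were seen, were Srxn1 (2.25 ± 0.37, SE), which encodes the peroxiredoxin-repairing sulfiredoxin, the efflux pump gene Abcc4 (1.19 ± 0.24), the glutathione transferase gene Gstp1 (0.88 ± 0.22), the aldehyde reductase gene Akr7a3 (0.86 ± 0.16), the thioredoxin reductase gene Txnrd1 (0.51 ± 0.13), the pentose phosphate enzyme gene Tkt (0.42 ± 0.09) and Gsta3 (0.42 ± 0.10). Probes of a gene differed in size for Srxn1 (1.14 on a second probe) and Gsta3 (0.49 and 1.80 on others). The list of conjugating enzymes also rose. It shares glutathione transferase genes such as Gsta3 and Gstp1 with the Nrf2 list, so these results are not independent. Its median was 0.26, with positive values in 30 of 34 members (camera adjusted p = 2.4e-04, and adjusted p = 0.579 with an estimated correlation). That median was 0.16 without corn oil replicate 3 and 0.15 after quantile normalization (adjusted p = 0.0180), and the list did not pass without the filter on dim probes (adjusted p = 0.157). Of its members 1 rose adjusted over the list alone, the glutathione transferase zeta gene Gstz1 (0.55 ± 0.08), and over all genes 0 did. Its largest value was that of the glucuronosyltransferase gene Ugt2b7, 2.27 ± 0.81 (limma adjusted p = 0.249), which was 3.09 without anthraquinone replicate 1 and 1.54 without anthraquinone replicate 3. Among efflux transporters, which did not shift as a list (camera adjusted p = 0.560), Abcc2 (1.40 ± 0.37), Abcc4 and Abcb1b (1.05 ± 0.25) rose and Abcb1a (-0.73 ± 0.17) and Abcc6 (-0.36 ± 0.11) fell when adjusted over the list alone, and 0 of the 10 passed over all genes. Abcb1a and Abcb1b are close paralogs whose probes were not told apart here, and other Abcb1b probes gave 0.75 and 2.74.

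The classical targets of the aryl hydrocarbon receptor Cyp1a1, Cyp1a2 and Cyp1b1, which encode xenobiotic-oxidising cytochromes P450, were not well above background on any array of either group. The same held for Cyp2b1 and Cyp3a9, marker genes of the receptors CAR and PXR. The 6 measured aryl hydrocarbon receptor targets did not shift as a list in camera (median 0.12, camera adjusted p = 0.285), and Nqo1 was the 1 member that rose, both over all genes and adjusted over the list alone. Fry called this list higher (fry adjusted p = 0.0423). Nqo1, which is also on the Nrf2 list, was its only member with an unadjusted limma p under 0.05. The CAR and PXR list did not shift in camera either (median 0.05, mean -0.28, camera adjusted p = 0.950, direction down). Of its members Abcc2 rose, and Abcb1a and the steroid hydroxylase gene Cyp2c11 (-4.53 ± 1.17, SE) fell, adjusted over the list alone. Cyp2c11 was -5.84 without anthraquinone replicate 1 and -3.67 without anthraquinone replicate 3. Over all genes 0 of its 11 members passed.

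The unfolded protein and amino acid response list did not shift as a whole (median 0.08, camera adjusted p = 0.123), and 0 of 35 members passed over all genes. The 5 members that rose adjusted over the list alone were the stress-response gene Nupr1 (2.67 ± 0.59, SE), the asparagine synthetase gene Asns (2.41 ± 0.49), the mitochondrial folate enzyme gene Mthfd2 (2.02 ± 0.45), Herpud1 (0.58 ± 0.14) and the transcription factor gene Ddit3 (0.51 ± 0.12). The values of the 3 largest leaned on anthraquinone replicate 3, without which Nupr1 was 1.98, Asns 1.81 and Mthfd2 1.49. Without anthraquinone replicate 2 or 3 the list passed upward, with adjusted p of 0.0412 and 0.0331.

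Cell cycle and mitosis genes rose as a list, with a median of 0.21 and positive values in 30 of 35 members (camera adjusted p = 1.4e-05, and adjusted p = 0.579 with an estimated correlation). The mitotic kinesin gene Kif2c (0.66 ± 0.08, SE), the cyclin gene Ccnb2 (0.46 ± 0.08) and the cytokinesis gene Prc1 (0.45 ± 0.10) rose adjusted over the list alone, and over all genes 0 did. The list did not pass without the filter on dim probes (adjusted p = 0.0754). A second probe of Kif2c gave -0.25 and one of Prc1 gave -0.11. DNA replication genes did not shift as a list (median -0.01, camera adjusted p = 0.824), and adjusted over the list alone the thymidine kinase gene Tk1 (0.37 ± 0.08) rose. Targets of p53 rose as a list by a median of 0.11 over 31 members (camera adjusted p = 0.0293, and adjusted p = 0.579 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. The p53 list did not pass without the filter (adjusted p = 0.311) or without moderation (adjusted p = 0.114). Its largest value was that of the stress cytokine gene Gdf15, 1.64 ± 0.32. The p53 targets Cdkn1a, Mdm2 and Ccng1, which act in cell cycle arrest and p53 feedback, had values of 0.11, 0.12 and 0.25 on their brightest probes, and the cyclin gene Ccnd1 0.13, none past the test. Dimmer probes of these targets gave larger values, 1.85 ± 0.45 and 1.35 ± 0.34 for Cdkn1a, 1.82 ± 0.60 for Ccng1 and 0.29 ± 0.07 for Mdm2 (SE), so the level of Cdkn1a and Ccng1 was not settled by these probes. With the mean of a gene's probes Cdkn1a was 1.105 and Ccng1 1.04, neither past the test.

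Markers of tubular injury did not move one way (median -0.06 over 37 members, camera adjusted p = 0.593). This test asks for 1 shared direction, so it cannot show an injury in which some members rise and others fall. Fry regardless of direction gave adjusted p = 6.8e-04 for this list, and 1.7e-04 for the proximal tubule metabolism list. It also gave low adjusted p for lists of other kinds, such as DNA replication (6.8e-04), mesangium and vascular smooth muscle (2.05e-04) and the circadian clock (0.0231). Hmox1 is a member of the injury list and Glyatl1 of the metabolism list, and both passed over all genes. This test therefore does not single out injury. The injury marker Havcr1, encoding kidney injury molecule 1, had a value of 1.24 ± 0.80 (SE, limma adjusted p = 0.466), which was 0.27 without anthraquinone replicate 3 and 1.86 without anthraquinone replicate 1, and Clu, Lcn2 and Spp1, which encode clusterin, lipocalin 2 and osteopontin, had values of 0.27, 0.19 and -0.06, none past the test. Over all genes 1 member rose, Hmox1. Adjusted over the list alone 3 members rose, Hmox1, Gpnmb (1.18 ± 0.15), a glycoprotein gene of lysosome-rich cells, and Gstp1, and 3 fell, the vitamin D-binding protein gene Gc (-3.35 ± 0.60, and -2.73 without anthraquinone replicate 2), Rgn (-1.42 ± 0.36) and Prom1 (-1.41 ± 0.33). Interferon-stimulated genes fell as a list, with a median of -0.21 and positive values in 5 of 31 members (camera adjusted p = 2.4e-04, and adjusted p = 0.579 with an estimated correlation), though 0 members passed over all genes or adjusted over the list alone, and the largest value was -0.76 for Rtp4, which was -0.33 without corn oil replicate 1 and -0.46 without anthraquinone replicate 3. The median of this list was -0.32 without corn oil replicate 2 and -0.13 without corn oil replicate 3 or with the normexp correction. Among chemokine genes, Ccl2, which encodes a monocyte attractant, fell by 1.09 on the log2 scale when adjusted over the list alone. The macrophage gene Cd68 and the collagen gene Col1a1 had values of 0.10 and -0.27, neither past the test.

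Collecting duct principal cell markers fell as a list, with a median of -0.45 over 9 members (camera adjusted p = 0.00217, and adjusted p = 0.579 with an estimated correlation). The median ranged from -0.54 to -0.22 over 22 settings, and the list lost its call in 2 of them. Adjusted over the list alone 5 fell and 1 rose, and over all genes 0 passed. The sodium channel subunit gene Scnn1b (-0.72 ± 0.09, SE), the glucocorticoid-inactivating enzyme gene Hsd11b2 (-0.49 ± 0.15) and the transcription factor gene Gata2 (-0.45 ± 0.11) were among those that fell, the water channel gene Aqp3 (0.46 ± 0.11) rose, and Aqp2, the vasopressin-regulated water channel gene, had a value of -0.34 (limma adjusted p = 0.301). Intercalated cell markers did not shift (median -0.05 over 14 members, camera adjusted p = 0.635). Podocyte markers fell by a median of 0.14 on the log2 scale over 14 members (camera adjusted p = 0.00555, and adjusted p = 0.579 with an estimated correlation). The cell cycle inhibitor gene Cdkn1c (-0.45 ± 0.11) and the semaphorin gene Sema3g (-0.33 ± 0.09) were among those that fell adjusted over the list alone, and over all genes 0 did. Thick ascending limb markers fell by a median of 0.15 on the log2 scale over 10 members (camera adjusted p = 0.0463, and adjusted p = 0.579 with an estimated correlation), with 0 members past either test. The claudin gene Cldn16 had the largest value, -0.40, which was -0.23 without corn oil replicate 2 and -0.24 without anthraquinone replicate 2, and Egf and Umod, genes of this segment, had values of -0.21 and -0.03. The fall of the thick ascending limb list was lost in 10 of 22 settings, among them leaving out corn oil replicate 1 (adjusted p = 0.126, as with the slide as a block), corn oil replicate 2 (0.0904), anthraquinone replicate 2 (0.261) or anthraquinone replicate 3 (0.0987). After quantile normalization its median was -0.31 (adjusted p = 0.00246). The principal cell and podocyte lists passed with the slide as a block (0.00135 and 0.00341), and the podocyte median was -0.09 without corn oil replicate 3. Over the 22 settings the podocyte median ranged from -0.18 to -0.06, and that list lost its call in 3 of them.

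Proximal tubule transporter genes moved in both directions without a shift of the list (median 0.04, mean -0.13, camera adjusted p = 0.712, direction down). Adjusted over the list alone 3 of 49 rose, the sulfate transporter gene Slc26a1 (0.65 ± 0.14, SE), the organic anion transporter gene Slc17a3 (0.62 ± 0.13) and the aquaglyceroporin gene Aqp7 (0.34 ± 0.08), and 4 fell, the sugar transporter gene Slc5a10 (-1.70 ± 0.31), the peptide transporter gene Slc15a2 (-0.999 ± 0.20), the steroid transporter subunit gene Slc51a (-0.83 ± 0.18) and the GABA transporter gene Slc6a13 (-0.60 ± 0.07). Over all genes 0 passed. The organic anion transporter genes Slc22a6 and Slc22a8 had values of 0.10 and 0.11, which became -0.06 and -0.09 after quantile normalization, and the anion transporter genes Slco1a1 and Slco1a6 had values of -1.31 ± 0.41 and -1.77 ± 0.53 (limma adjusted p = 0.220 and 0.216). Endocytic receptor and brush border genes did not pass as a list (median -0.07, camera adjusted p = 0.220), but did after quantile normalization (median -0.11, adjusted p = 0.00243). The peptidase genes Ace (-0.998 ± 0.11) and Anpep (-0.78 ± 0.16) fell adjusted over the list alone, over all genes 0 did, other Ace probes gave -1.61 and -1.65, and the endocytic receptor gene Lrp2 had a value of -0.20, which was -0.05 without anthraquinone replicate 3, -0.13 without corn oil replicate 3 and -0.30 without anthraquinone replicate 1. Among 47 proximal tubule metabolism genes, which did not shift as a list (camera adjusted p = 0.712), Glyatl1 fell over all genes, and adjusted over the list alone Glyatl1 and the pyrimidine-degrading enzyme gene Dpys (-0.48 ± 0.09) fell.

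Respiratory chain genes rose as a list, with a median of 0.17 and positive values in 46 of 47 members (camera adjusted p = 9.5e-11, and adjusted p = 0.579 with an estimated correlation), and the largest value was that of the complex I subunit gene Ndufa10, 0.38 ± 0.16 (SE). Lysosome and autophagy genes rose by a median of 0.13 over 43 members (camera adjusted p = 7.8e-04, and adjusted p = 0.579 with an estimated correlation), and adjusted over the list alone Gpnmb and the autophagy receptor gene Sqstm1 (0.71 ± 0.12) rose. PPAR-alpha targets, which act in fatty acid oxidation, rose by a median of 0.17 over 34 members (camera adjusted p = 0.00803, and adjusted p = 0.816 with an estimated correlation). The largest value among them was that of the hormone gene Fgf21, 3.74 ± 1.15, with 1 of the 3 corn oil arrays well above background. It was 2.43 without anthraquinone replicate 3, 4.35 without anthraquinone replicate 1 and 4.43 without anthraquinone replicate 2. Over all genes 0 members of these 3 lists passed, and adjusted over the list alone 0 respiratory chain genes and 0 PPAR-alpha targets did. After quantile normalization the medians were 0.02, 0.03 and 0.05 with adjusted p of 0.570, 0.223 and 0.350, so none of the 3 lists passed. In the main setting their medians lay at percentiles 88.7, 98.3 and 99.7 of the level-matched random lists, in the same order. Without the filter on dim probes the lysosome and PPAR-alpha lists did not pass either (adjusted p = 0.206 and 0.261). The list of PPAR-alpha targets also did not pass with the slide as a block (adjusted p = 0.121) or without anthraquinone replicate 3 (adjusted p = 0.439). Its median was 0.11 without corn oil replicate 1, 0.35 without anthraquinone replicate 1 and 0.07 without anthraquinone replicate 3.

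Erythroid genes rose as a list, with a median of 0.66 and positive values in 10 of 10 members (camera adjusted p = 2.1e-04, and adjusted p = 0.579 with an estimated correlation). Adjusted over the list alone 5 rose, the haem synthesis gene Alas2 (0.86 ± 0.21, SE), the globin genes Hbb-b1 (0.69 ± 0.14), Hbb (0.66 ± 0.14) and Hba-a1 (0.66 ± 0.15), whose paralogs were not told apart here, and Slc4a1 (0.35 ± 0.10), which is also an intercalated cell marker. Over all genes 0 passed. Neutrophil and mast cell genes did not shift (median -0.12 over 8 members, camera adjusted p = 0.285).

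Of the 50 lists, 12 passed, 8 higher and 4 lower. The other 38 had adjusted p between 0.0718 and 0.990. With an estimated correlation 0 of the 12 held in camera, and 2 lists had an unadjusted p under 0.05. Fry called 4 lists higher, those of Nrf2, aryl hydrocarbon receptor and p53 targets and of the respiratory chain. After quantile normalization 5 lists were higher and 5 lower, after cyclic loess, added after seeing the data, also 5 and 5, and after the normexp correction 7 and 9. With the slide as a block 7 were higher and 3 lower.

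**Figure D2:**
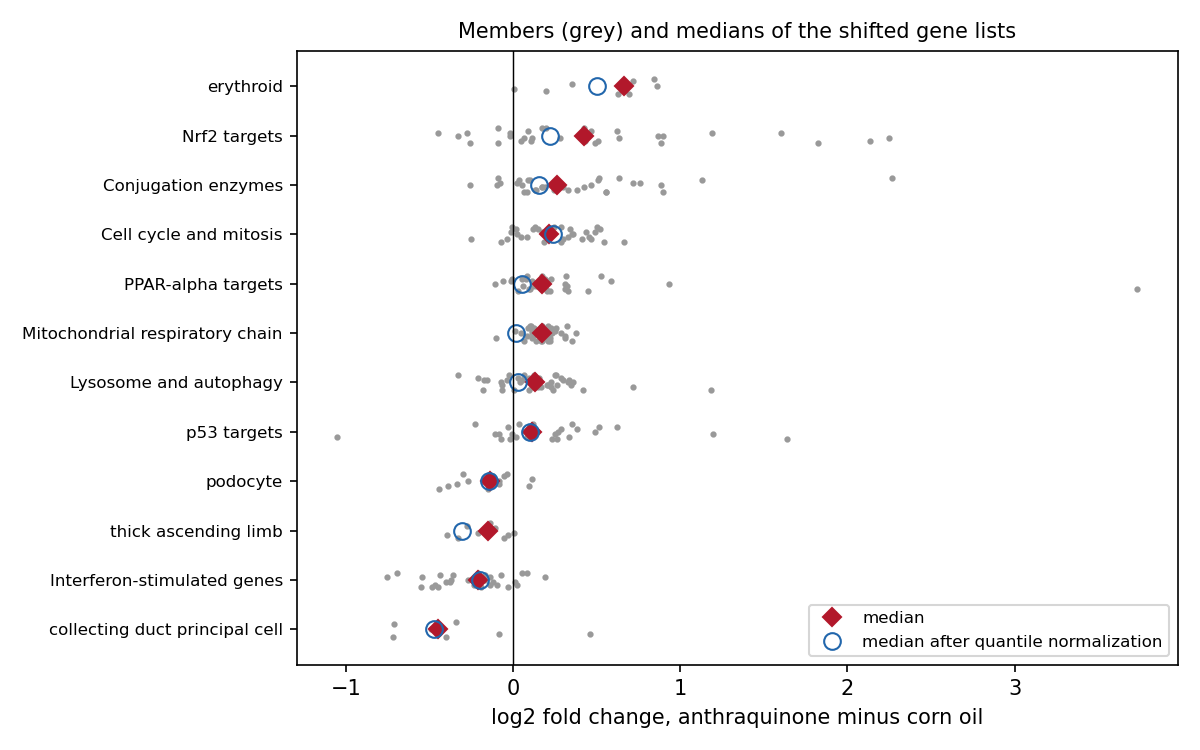
Log2 fold change, anthraquinone minus corn oil (horizontal axis), of the measured members (grey points) of the 12 lists past the camera threshold, with the list median (red diamonds) and the median after quantile normalization (open blue circles). The vertical position within a row only separates the points. The erythroid median lies at 0.66 and the principal cell median at -0.45, while the respiratory chain median moves from 0.17 to 0.02 after quantile normalization.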

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

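Control spots entered no comparison, and no test of a cause was chosen for them after their values were seen. The 308 negative control spots gave a median log2 signal, relative to each array's 75th percentile, between -8.08 and -7.89 in corn oil and between -7.54 and -7.30 with anthraquinone, a difference of 0.60, with every anthraquinone array above every corn oil array. Without that scaling, corn oil replicate 1 lay within the range of the anthraquinone arrays, with which it shares row 2. Corn oil replicates 2 and 3, in row 1, lay below that range. The separation by group thus rests on the scaling, and for the unscaled background, group and row on the slide are not told apart. Among the 10 kinds of spike-in control probe, 3 that were well above background on all arrays lay higher on every anthraquinone array than on every corn oil array, by 0.0907, 0.0950 and 0.124 on the log2 scale. Groups of 3 arrays separate completely in 10% of splits by chance.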

How the results depend on the processing

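The number of genes changed by anthraquinone, 9, became 6609 (6049 higher, 560 lower) without the filter on dim probes, 80 with a trended and robust variance, 14 with each probe on its own (not run for named genes and lists), 16 with the normexp correction (on median spot signals, since the planned mean signals could not be used), 2 with the slide block, and 1 with the row block (which leaves corn oil replicate 1 as the only control), without moderation or at the stricter threshold of 0.01. Leaving out each array gave 1 to 25. The cause was not tested for these, though the unfiltered test adds entries below background. The negative controls, which lie at that level, were 0.60 higher on the log2 scale with anthraquinone. List tests without the filter compare each list with those added entries too, so a list call lost there may reflect them. Replicate numbers did not pair the animals (same-numbered deviations correlated at 0.03, -0.06 and -0.01, and 1 of the 3 corn oil arrays correlated best with its own number), and the replicate block gave 1 changed entry and 13 lists. The count of 12 lists became 0 with an estimated correlation and 4 with fry, and was 10 to 15 when each array was left out. The cause was not tested.

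Normexp in this form and cyclic loess were chosen after seeing the data. Across 22 settings and 82 genes, the direction and the side of the threshold stayed in 1677 comparisons, 68 lost a call, 36 gained one and 18 turned, and across 21 lists the numbers were 399, 47, 8 and 8. Since only 9 entries passed in the main setting, most gene comparisons that stayed are of genes past the threshold in neither setting. Settings that changed only the threshold could not turn a direction. Hmox1 ranged from 1.91 to 2.42 with adjusted p from 0.00688 to 0.190, and Nqo1 from 1.43 to 1.91 and Glyatl1 from -1.52 to -0.97 with adjusted p up to 0.190. Of the 22 settings, Hmox1 passed in 11, Nqo1 in 12 and Glyatl1 in 12. The settings are not separate checks. The slide block repeats the test without corn oil replicate 1, the deposited value table repeats the main scaling, and a 2-fold minimum could drop none of these genes. Directions turned only for values that passed in neither setting. Slc22a6 was -0.0564 and Slc22a8 -0.0941 after quantile normalization, and -0.10 and -0.0813 after cyclic loess. Clu was -0.17 and Ccnd1 -0.0835 with the slide block, and Spp1 was 0.20, Umod 0.0576 and the intercalated cell list 0.0147 with the row block, each against corn oil replicate 1 alone. The tested direction of the CAR and PXR list, whose median is positive in the main setting, turned at medians of 0.0872 without the filter and 0.0515 with probes above background on all arrays or with fry, the efflux list at 0.0367 without the filter and the injury list at -0.0643 with fry. With an array left out, Clu ranged from -0.24 to 0.56, Ccnd1 from -0.0835 to 0.30, Lcn2 from -0.17 to 0.74, Umod from -0.15 to 0.16, Spp1 from -0.48 to 0.42, the gene list: CAR and PXR targets from 0.0182 to 0.0859 and the gene list: Tubular injury and regeneration markers from -0.12 to 0.0124. The cause was not tested.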

Other observations

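The comparisons with signal level, with blood leukocyte genes and with intercalated cells, those of added lists and list differences with arrays left out, and the topics of both added lists, were chosen only after the results were seen.

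Some of the largest values belonged to genes that did not pass over all genes and were chosen after their values were seen. The growth factor gene Areg had a value of 3.38 ± 0.61 (SE, limma adjusted p = 0.157), which was 2.65 without anthraquinone replicate 3. The fucosyltransferase gene Fut1 was not well above background on any corn oil array and was at least 10.2-fold higher with anthraquinone (limma adjusted p = 0.158). Its signal on anthraquinone replicates 1, 2 and 3 was -3.79, -3.24 and -0.78, so replicate 3 carries much of this bound.

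The rise of Asns, Mthfd2 and Nupr1, largest in anthraquinone replicate 3, led to the hypothesis that the ATF4 programme, which answers amino acid shortage, is active. A further 20 of its genes outside the fixed lists were written down before they were tested, and 16 were measured. All 16 were positive, with a median of 0.33 that lay at percentile 100 of the level-matched random lists (camera adjusted p = 2.6e-06 over the pair of added lists, but adjusted p = 0.413 with an estimated correlation). After quantile normalization the median was 0.29. Without anthraquinone replicate 3 the median was 0.21 with 16 of 16 positive (camera adjusted p = 1.3e-05, and adjusted p = 0.0367 with an estimated correlation), and with any other array left out the latter was 0.338 to 0.635. The values included 0.80 for Cars1, 0.65 for Eif4ebp1 and 0.58 for Yars1, and 0 members passed adjusted over the list alone. The result is consistent with the hypothesis, within what the strong correlation among these genes (0.725) allows. A list of glucocorticoid-induced genes, 11 of 12 measured, had a median of 0.13 at percentile 88.1 (camera adjusted p = 0.443). The median was 0.02, with the tested direction down, without anthraquinone replicate 2 and 0.29 without anthraquinone replicate 1, which leaves that hypothesis open.

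The respiratory chain rise came with a trend across signal levels. The median log2 change was -0.16 in the dimmest of 10 equal bins of signal and 0.15 in the brightest, and -0.08 and 0.01 after quantile normalization. The respiratory chain median lay at percentile 88.7 of random lists of the same signal level, and its median of 0.17 fell to 0.02 after quantile normalization, which ended the call. A scale difference that depends on intensity may account for this rise, while the slide of corn oil replicate 1 does not, since the list passed with the slide as a block (adjusted p = 5.5e-11). An effect of anthraquinone on these genes stays open.

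The erythroid rise lay at percentile 100 of level-matched random lists and passed after quantile normalization with a median of 0.50 (adjusted p = 1.9e-04), which argues against the trend across signal levels as its whole cause. More blood left in the tissue would raise blood leukocyte genes too, but the neutrophil and mast cell median differed from the erythroid one by -0.78, with a larger member SD of 0.39, and by -0.44 with an SD of 0.43 without anthraquinone replicate 1. Mast cells also reside in tissue, and the neutrophil genes S100a8 and S100a9 had values of -0.24 and -0.12. Csf3r, on the same list, fell adjusted over the list alone (-0.94 ± 0.22, SE), with 2 of the 3 anthraquinone arrays well above background. Of the 8 members 3 had positive values. The neutrophil and mast cell list had 8 members at a mean normalized log2 level of -2.33, against 1.32 for the erythroid list. So small and dim a list cannot exclude more blood in the tissue, which stays open. A change in the red cells of treated animals, such as a larger share of young ones, was not tested and stays open as well.

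The fall of principal cell genes was not matched by intercalated cells of the same duct. The medians differed by 0.40 with a larger member SD of 0.36, and Aqp3 moved against the other members. The difference was within that SD without corn oil replicate 3 (0.30 with an SD of 0.41) or anthraquinone replicate 2 (0.30 with an SD of 0.36), so less collecting duct in the samples may contribute and stays open. The list passed with the slide as a block (adjusted p = 0.00135). A change within principal cells after anthraquinone is open as well.

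The 10 splits of the 6 arrays into groups of 3 are too few for a share under 0.05. In 1 of them, the real one, the number of changed entries reached 9, and the highest of the others was 2. The number of lists reached 12 in 1 split, the real one, and the highest of the others was 10, so arrays grouped otherwise gave nearly as many list calls.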
